A study of Zea mays with 104 samples.

How the data were processed

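The labels describe nuclei of seedlings of 26 maize founder lines, pooled and loaded at 16000 input nuclei on each of 4 single-cell ATAC-seq libraries (10X Genomics chemistry version 1.1). They give 3 biological replicates of the pool, of which replicate 3 has 2 technical libraries, and mark founder samples as fresh or frozen. The submitters' processing notes name Cell Ranger and MACS2, with no version and no role for either. The design note says that cells were genotyped and that the reads of each founder were aggregated. How droplets with nuclei of more than 1 founder were treated is not given in the sources used here.

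The deposited file is a concatenated peak list with 1934350 entries in 51 lists, and it carries no cell, sample or summit. Each entry has the start and end of a peak in base pairs on the assembly that the authors named, in units other than a level. The deposited score is 10 times the -log10 q, reduced to a whole number, and entered no test. The deposited strength is a ratio, the fold enrichment of the peak over the local background of the authors' peak caller, and ran from 1.391 to 38.287. The authors' last values are the -log10 p and the -log10 q of the peak caller (neg_log10_p), of which the lowest were 3.183 and 1.302, as a q threshold of 0.05 gives. Peaks were 200 to 3944 bp wide, with 0 repeated and 0 overlapping intervals within lists. The list named MS37W was taken as the founder M37W of the labels, which its assembly name holds, and letter case was ignored for the other founder names.

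Depth is not stated in the file. The fold enrichment and -log10 p of the peak caller together fix the number of reads piled up at a peak and the background it was compared with, and a whole number of reads was recovered for 100% of the peaks within 0.001 of the -log10 p. The depth index of a list was its background over the whole genome, called its lowest background here. Most recovered backgrounds (99.6%) lay on steps of 0.02. The index was the most frequent rounded value among the others, so it rests on a small part of the peaks. This index was chosen after the file was seen. It is a relative depth and gives neither reads nor nuclei per founder, so no counting interval was given for a peak.

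Genes came from the reference gene table of the same B73 assembly, with 47019 genes on the 10 chromosomes (33681 protein-coding). The table has no strand, so the planned promoter window became both gene ends, from 1 kb outside to 500 bp inside. Chromosome length was the end of the last peak or gene, 2130.84 Mb in all. Peaks were genic when they overlapped a gene by at least 1 bp, near within 2 kb, and distal otherwise. For comparison, the same intervals were placed at random on their chromosome 100 times. Merged regions joined peaks of all founders that overlapped by at least 1 bp, on chromosomes 1 to 10.

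Of 402 entries in the 14 gene lists, 229 matched a single gene by symbol or synonym, 154 matched none and 16 matched more than 1 gene. A further 1 named the gene of another entry. The remaining 2 were left out after names were matched and before peaks were looked at: dit1, whose alias omt1 names another gene, and mez1, which had been listed by mistake. Genes to be named were fixed by a rule: from each list the 3 with a peak in most founders, then the highest mean fold enrichment, and alphabetically up to 2 with no peak in any founder. The rule also took the 10 peaks of B73 with the highest fold enrichment. Of the genes that the rule takes, 1 is not reported here. Other names are given as chosen after their values were seen.

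Founders, with 1 list each, were the unit of tests of differences and relations, genes that of the gene list tests, and merged regions that of tests of regions held by 1 pair of founders. Differences over founders were tested by two-sided sign-flip permutation (100000 resamples). Relations were tested by Pearson and Spearman correlation with permutation p (100000 resamples). Similarity of pairs was tested by a Mantel test (10000 permutations), gene lists by two-sided Fisher exact tests, and multiple tests were adjusted by the Benjamini-Hochberg method. Seeds were fixed at 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated data, the pileup was recovered for 100% of 19858 peaks and the number of lists per region was right for 100% of 2000 regions. The sign-flip test called 5.2% of data with no effect and 99.8% of data shifted by 1 SD. The gene list test called 0.5% of 1300 lists with no effect and 99% of 100 with one, for 23 genes at 98% against 60%. Shorter lists with an effect were not simulated.

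Alternatives set beforehand covered a stricter threshold (the 50% of peaks with the highest -log10 q, from 17.4), chromosomes only, a middle of 20%, lists of equal length (28686 peaks), windows of 1 kb or 2 kb, coding genes only, a reciprocal overlap of 50%, the overlap coefficient, all annotated genes as background, and leaving out Mo18W and Oh43. Alternatives chosen after the file was seen covered the own assemblies, leaving out B73, the midpoint of a peak, the background level in place of peak number, the first name of an entry, and genes whose windows reach no other gene. Replicates and summits were not compared, since the file does not hold them. Fresh and frozen samples were not compared, since the lists of 24 founders hold both and those of Mo18W (fresh) and Oh43 (frozen) also differ in founder. Peaks on unplaced scaffolds entered the totals of the lists, and so the comparisons of peak number, but none of position, sharing or genes.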

Results

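The data described accessible chromatin in seedling nuclei of the 26 inbred maize lines that are parents of the nested association mapping population, the NAM founders, among them the reference line B73. Nuclei of all founders were pooled, each nucleus was assigned to its founder by genotype, and the reads of each founder were aggregated into 1 set. The labels gave 104 samples, of which 100 belonged to single founders (50 fresh and 50 frozen) and 4 to the pool. A total of 24 founders had 4 samples each, fresh and frozen, while Mo18W had 2 fresh samples only and Oh43 had 2 frozen samples only. The labels put fresh samples first in most founders with both states, but frozen samples first in Ms71, NC350 and NC358. These stand between Mo18W and Oh43 in the order of the labels. Whether the tissue states from Mo18W to Oh43 are labelled correctly could not be checked. The file held 51 peak lists, 26 in the coordinates of the B73 genome (Zm-B73-REFERENCE-NAM-5.0) and 25 in the assembly of the founder itself. Each founder thus had 1 list per genome and no replicate error, and an error given over founders is a spread between founders. Positions below are in B73 coordinates unless the own assembly is named.

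B73 had the most accessible regions called, with 50486 peaks, and CML228, a tropical line, had the fewest, with 28733. The median founder had 37558 peaks (mean 37625.8 ± 6015.2, SD, n = 26), which covered a median of 17.2 Mb. Oh43 had the widest peaks, with a median of 549 bp and 31.7 Mb covered, and CML228 the narrowest, with a median of 329 bp and 10.5 Mb covered. The read depth of a founder was read from the lists as the lowest background of the peak caller, in reads per position. It ran from 0.297 in Mo18W to 4.742 in Oh43, a 15.97-fold range, with a median of 0.7065. These extremes are the founders labelled with 1 tissue state each, so that founder and tissue state cannot be separated in them. Among the 24 others the level ran from 0.304 in CML228 to 4.198 in B73. The median number of reads piled up in a peak was 15 in CML228 and 110 in Oh43.

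Founders with more peaks had wider peaks with lower fold enrichment over background, the strength value that the authors' peak caller gave each peak. Across the 26 founders, log2 peak number and median width had a Pearson r of 0.891 and a Spearman rho of 0.838, and r without B73 and Oh43 was 0.865. For median fold enrichment, which ran from 5.09 in Oh43 to 7.6 in CML247, r was -0.684 and rho was -0.534, and r without B73 and Oh43 was -0.569. For the background level, r was 0.923 and rho was 0.890, and r without B73 and Oh43 was 0.926. For the median pileup, r was 0.909 and rho was 0.866, and r without B73 and Oh43 was 0.884. These 4 relations formed 1 family. The two-sided permutation p of width, background and pileup was 1e-05 for r and rho, the smallest the permutations can give (Benjamini-Hochberg adjusted p = 1.33e-05). For fold enrichment it was 2e-05 for r (adjusted p = 2e-05) and 0.00508 for rho (adjusted p = 0.00508). Among the 24 founders with 4 samples, r was 0.877 for width, -0.645 for fold enrichment, 0.918 for background level and 0.897 for pileup.

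**Figure D1:**
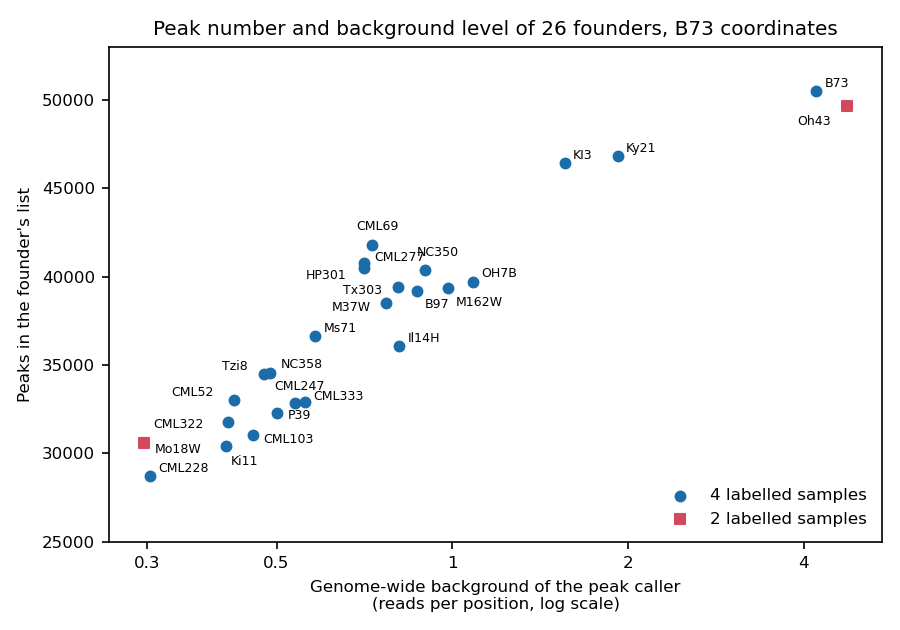
Number of peaks in the list of each founder (y axis) against the genome-wide background of the peak caller (x axis, reads per position, log scale), 1 point per founder, squares for the founders with 2 samples. Founders with a higher background have more peaks (r = 0.923 on log2 values), between 28733 in CML228 and 50486 in B73.

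Accessible regions were denser in the outer parts of the chromosomes than in the middle. In the outer 60% of the 10 chromosomes the founders had 22.6 ± 3.72 peaks per Mb (SD, n = 26), and in the middle 40% 10.2 ± 1.51 peaks per Mb. The difference was 1.14 ± 0.051 on the log2 scale, or 2.20-fold, and was present in 26 of 26 founders, from 1.02 in CML228 to 1.24 in Oh43. Protein-coding genes showed a ratio of 2.02, with 19.8 per Mb in the outer and 9.80 per Mb in the middle part. Among chromosomes, chromosome 5 had the highest density (20.5 ± 3.33 peaks per Mb) and chromosome 4 the lowest (14.7 ± 2.40 peaks per Mb). The two-sided sign-flip permutation test of outer against middle gave p = 1e-05, the smallest it can give. Founders share ancestry and came from 1 pool, so tests over founders treat as independent what is partly not.

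Most peaks lay in or near genes. On average 53.6% ± 1.64 of the peaks of a founder overlapped an annotated gene (SD, n = 26), against 10.9% of the same intervals placed at random on their chromosome, a ratio of 4.94. A further 20.7% ± 0.897 lay within 2 kb of a gene, against 6.29% at random, a ratio of 3.29. The remaining 25.7% ± 0.843 were distal, farther than 2 kb from any gene, against 82.9% at random, a ratio of 0.310. B73, on whose assembly the genes were annotated, had the highest genic share (57.0%) and the lowest distal share (23.9%). Mo18W, with fresh samples only, had the lowest genic share (48.1%) and the highest distal share (28.5%). In each of the 26 founders the distal share was below that of all 100 random sets.

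In B73, protein-coding genes had peaks at their ends in a larger share than the other classes of genes named here, a comparison that was not tested. Because the gene table gave no strand, a gene counted as having a peak when a peak reached from 1 kb outside to 500 bp inside either annotated end. In B73, 20325 of 33681 protein-coding genes (60.3%) had such a peak, and the mean over founders was 51.0% ± 4.77 (SD, n = 26). A total of 8229 coding genes (24.4%) had one in every founder and 8703 (25.8%) in none. Among the 50% of peaks with the highest -log10 q, the share in every founder was 6.06% of coding genes outside the C4 list described below. In B73 the share was 50.9% of 914 tRNA genes, 50% of 164 miRNA genes, 37.3% of 241 snRNA genes and 30.4% of 642 snoRNA genes. It was 20.3% of 5320 lncRNA genes, 13.2% of 3783 pseudogenes and 0.679% of 884 rRNA genes. These windows reached another annotated gene for 10240 coding genes (30.4%).

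Regions with a peak in every founder lay at genes more often than regions with a peak in 1 founder alone. The peaks of all founders merged into 81864 regions, which covered 50.2 Mb. Of these, 11214 (13.7%) had a peak in every founder, 17375 (21.2%) in at least 24 founders, and 18774 (22.9%) in 1 founder only. Among the peaks of a founder, 34.7% ± 6.44 of those in its private regions were distal, against 21.3% ± 0.465 of those in regions of every founder (SD, n = 26). The difference was 13.4 ± 6.14 percentage points and positive in 25 of 26 founders, with p = 1e-05 in a two-sided sign-flip permutation test, the smallest it can give. B73 was the exception, with 16.1% of its private peaks distal against 20.01% of its peaks in regions of every founder, a difference of -3.95 points. B73 was also the only founder compared here in the coordinates and gene annotation of its own genome. The genic share was 44.4% ± 6.68 in private regions and 59.6% ± 2.21 in regions of every founder, and CML52 alone had the higher share in its private regions (60.05% against 58.5%). Merged regions had a median width of 252 bp in 1 founder and 914.5 bp in every founder. Peaks in regions of 1 founder were also weaker, with a median fold enrichment of 4.98 and -log10 q of 6.91. In regions of every founder these were 8.73 and 29.5. Whether the difference in position remains between peaks of equal strength was not tested.

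Private accessible regions were most frequent in Oh43, where they held 2294 peaks or 4.62% of its list, and in CML228, where they held 1230 peaks or 4.29%. B73 had 1401 peaks in private regions. Oh43 and B73 also had the highest background levels (4.742 and 4.198), while that of CML228 was low (0.304). Whether private peaks were missed in other founders for lack of depth was not tested. OH7B had the lowest share, with 375 peaks or 0.944%. Of the regions that all other founders had, CML228 lacked the most and had 90.7% of them, followed by Mo18W with 93.6% and CML103 with 96.97%. CML228 and Mo18W also had the lowest background levels (0.304 and 0.297). Whether the missing regions were closed or not detectable at that depth was not tested. These regions are in B73 coordinates, so open sequence of other founders that the B73 genome lacks was not counted. With founders added in random order, the number of regions rose from 35110.8 with 1 founder to 81864 with 26, and the last founder added 717. The number in every founder fell to 11214. The counts depended on the threshold and on the definition of overlap: the regions of every founder numbered 2627 among the 50% of peaks with the highest -log10 q, and private regions numbered 32627 with a reciprocal overlap of 50%.

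**Figure D2:**
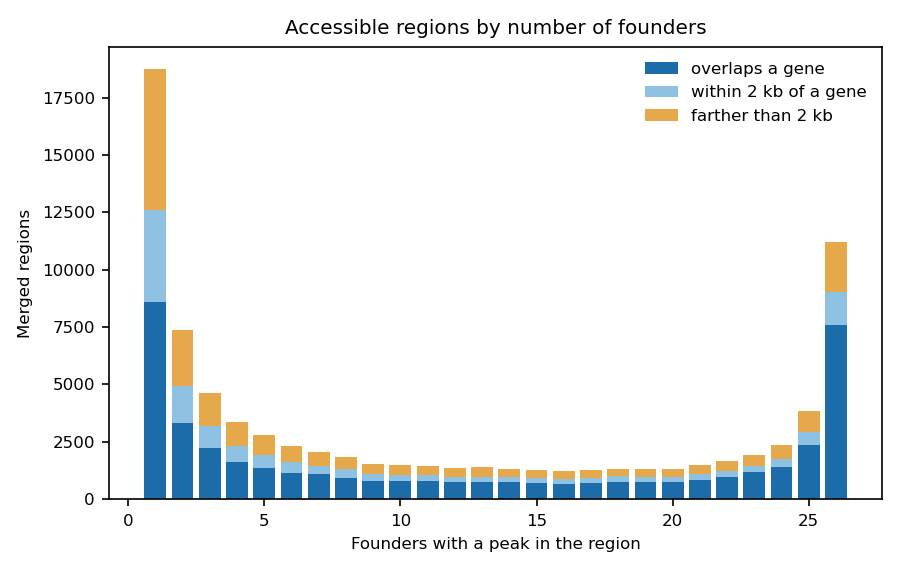
Number of merged regions (y axis) by the number of founders with a peak in them (x axis), with colours for regions that overlap a gene, lie within 2 kb of one or lie farther away. The 18774 regions of 1 founder and the 11214 regions of all 26 founders are the tallest bars.

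**Figure D3:**
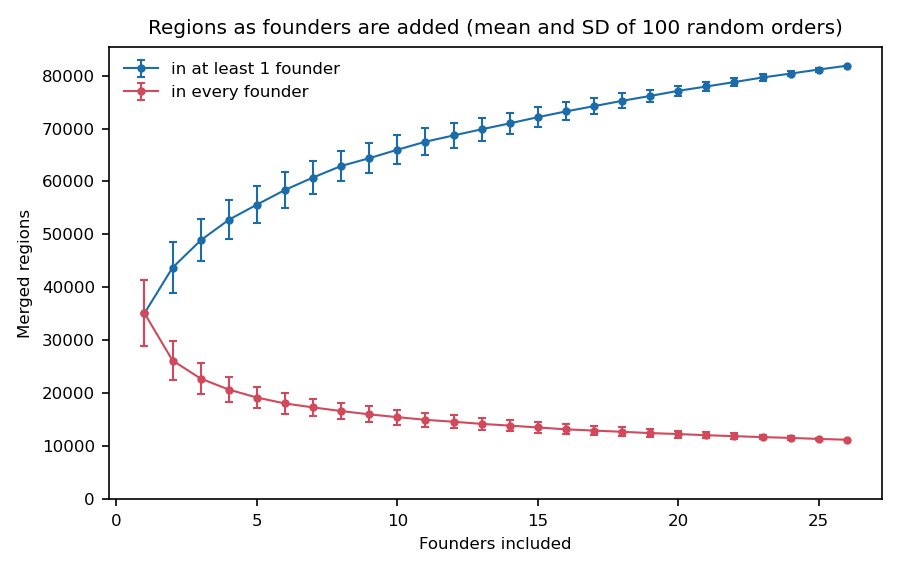
Number of merged regions in B73 coordinates found in at least 1 founder and in every founder (y axis) as founders are added (x axis), as mean and SD of 100 random orders. The upper curve ends at 81864 regions and the lower at 11214.

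The most alike pair of founders was Ky21 and Oh43, with a Jaccard index (shared over total covered length) of 0.631. B73 and KI3 (0.630), B73 and Oh43 (0.629) and KI3 and Ky21 (0.626) were close behind. Ky21, Oh43, B73 and KI3 had the highest background levels of all founders, from 1.557 in KI3 to 4.742 in Oh43. Likeness and depth thus cannot be told apart in these pairs. The least alike pair was CML228 and Oh43, with 0.263. The index cannot exceed the ratio of the shorter to the longer covered length, here 10.5 Mb in CML228 and 31.7 Mb in Oh43. Pairs with very unequal covered lengths were thus bound to a low index, however much of the shorter list was shared. Over all 325 pairs the mean was 0.498 ± 0.0636 (SD). Pairs with a larger difference in log2 peak number had a lower Jaccard index, with a Mantel r of -0.752 and p = 1e-04, the smallest that 10000 permutations of founder labels can give. Additive effects of the 26 founders held 66.1% of the variance of the log2 index. With the overlap coefficient (shared length over the shorter covered length) the relation had the opposite sign, with a Mantel r of 0.756, so the direction rests on the measure of similarity.

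Genes of photosynthesis and of core cell functions were the groups whose ends were open most uniformly. Each of 14 gene lists, fixed before the data were examined, was compared with all other protein-coding genes by a two-sided Fisher exact test, for peaks in B73 and for peaks in every founder, with Benjamini-Hochberg adjustment over the 28 tests. The lists held 229 matched genes, and the windows of 49 of them reached another gene. A total of 5 tests from 3 lists passed an adjusted p of 0.05. With all annotated genes in place of coding genes as background, 9 passed, which added the B73 tests of epidermis, leaf patterning, flowering time and light signalling. Fold enrichments below are means over the founders with a peak, with SD.

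Core cell functions passed in both tests. All 33 genes (100%) had an end peak in B73, against 60.3% of other genes (exact test, adjusted p = 9.83e-07), and 23 (69.7%) had one in every founder, against 24.4% (adjusted p = 9.83e-07). The strongest were h4c7, a histone H4 gene on chromosome 10 (137432648 to 137433262), at 16.02 ± 1.96, pcna1, the sliding clamp of DNA replication, at 15.4 ± 2.32, and gpc4, a cytosolic glyceraldehyde-3-phosphate dehydrogenase, at 14.1 ± 1.74 (n = 26 each). The window of h4c7 also reached another gene. The remaining 10 genes had end peaks in some founders, and none lacked one in all founders. With the 50% of peaks highest in -log10 q, 13 of 33 (39.4%) had one in every founder, against 6.03% (exact test, adjusted p = 3.65e-07).

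Light harvesting and photosystem genes also passed in both tests. All 13 had an end peak in B73 (exact test, adjusted p = 0.0146) and 12 (92.3%) had one in every founder (adjusted p = 4.23e-06). With the 50% of peaks highest in -log10 q, 5 (38.5%) had one in every founder, against 6.05% (exact test, adjusted p = 0.00648). The exception in the whole lists was lhcb3, chosen here after its values were seen, which lacked a peak in Tzi8. Fold enrichment was 14.6 ± 1.72 at cabm1, a chlorophyll a/b binding protein gene on chromosome 8 (145361964 to 145363001), 11.8 ± 2.17 at lhcb6, an antenna protein of photosystem II, and 10.97 ± 2.14 at psan1, a subunit of photosystem I (n = 26 each). Among the 7 genes whose windows reached no other gene, the B73 test no longer passed, with 7 of 7 against 57.7% (exact test, adjusted p = 0.122), while the test in every founder did, with 6 of 7 (adjusted p = 0.00701).

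The 5 C4 and Calvin cycle genes all had an end peak in every founder (100% against 24.4%, exact test, adjusted p = 0.00609). In B73 all 5 thus also had one (100% against 60.3%), the highest share possible. With 5 genes even that share could not pass (exact test, p = 0.164, adjusted p = 0.271), so the B73 test decides nothing. Fold enrichment was 7.87 ± 1.202 at mdh6, the chloroplast malate dehydrogenase of the C4 cycle, 7.61 ± 1.49 at gpa1, a subunit of the chloroplast glyceraldehyde-3-phosphate dehydrogenase, and 7.57 ± 1.89 at rca1, Rubisco activase (n = 26 each). The window of rca1 also reached another gene. Among the 50% of peaks with the highest -log10 q, 0 of the 5 genes had a peak in every founder and the call was lost (exact test, adjusted p = 1). In B73 all 5 kept a peak at that threshold, which was the same for all lists whatever their depth.

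**Figure D4:**
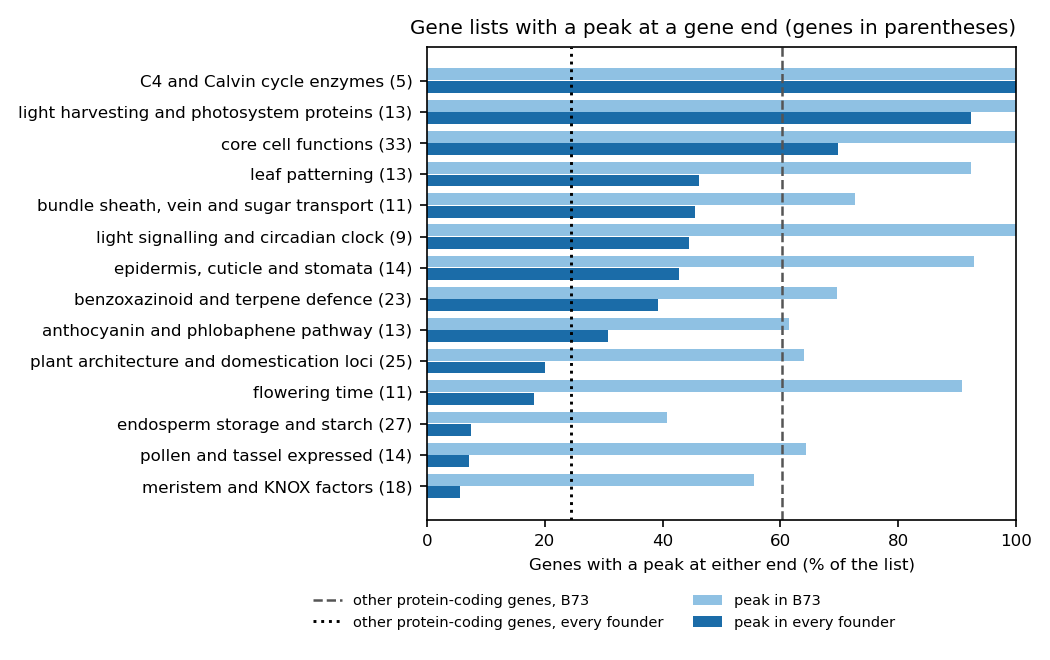
Share of the genes of each list with a peak at either end (x axis, percent), in B73 (light bars) and in every founder (dark bars), with the number of genes in parentheses. Dashed and dotted lines mark the other protein-coding genes, 60.3% in B73 and 24.4% in every founder.

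The circadian clock genes gi1 and gi2 had the highest mean fold enrichment of all list genes, but their list, light signalling and circadian clock, did not pass. All 9 had an end peak in B73 (exact test, adjusted p = 0.0567) and 4 had one in every founder (adjusted p = 0.347). Fold enrichment was 19.6 ± 2.41 at gi1 and 19.4 ± 2.35 at gi2, the maize GIGANTEA genes of the circadian clock, on chromosome 8 (21695212 to 21703434) and chromosome 3 (9234026 to 9245231), and 12.1 ± 1.54 at phya2, a phytochrome A gene (n = 26 each). The window of gi2 also reached another gene. Among the 50% of peaks with the highest -log10 q, the B73 test passed (9 of 9, exact test, adjusted p = 0.0355).

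Genes of leaf form and surface were mostly open in B73, and neither list passed. Of the epidermis, cuticle and stomata genes, 13 of 14 had an end peak in B73 (exact test, adjusted p = 0.0567) and 6 in every founder (adjusted p = 0.243), with 13.9 ± 2.59 at brk3, a gene of epidermal cell lobing, 10.0 ± 1.58 at ocl4, an epidermal homeodomain factor, and 8.06 ± 1.07 at gl8, a gene of leaf wax synthesis. Of the leaf patterning genes, 12 of 13 had one in B73 (exact test, adjusted p = 0.0723) and 6 in every founder (adjusted p = 0.213). Fold enrichment was 14.5 ± 1.68 at grf10, a growth-regulating factor, 10.4 ± 0.977 at rld1 and 8.39 ± 1.75 at rld2, homeodomain factors of the upper leaf side. The windows of gl8, rld1 and rld2 also reached another gene, and lg2, a gene of the ligule, had no end peak in any founder. With windows of 2 kb outside the gene, epidermis genes passed in B73 (14 of 14, exact test, adjusted p = 0.0102) and leaf patterning genes in every founder (8 of 13, adjusted p = 0.0495).

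Of the 11 flowering time genes, 8 had an end peak in some founders and not in others, and the list did not pass. Of the 11, 10 had an end peak in B73 (exact test, adjusted p = 0.151) but 2 in every founder (adjusted p = 1), namely zcn18 at 10.9 ± 2.50 and mads69 at 8.81 ± 1.32 (n = 26 each). The CONSTANS-like gene conz1 had a peak in 25 founders (10.8 ± 2.09), all but CML103. No founder had an end peak at zcn2, of the family of floral activators and repressors that resemble FT and TFL1. Of the bundle sheath, vein and sugar transport genes, 8 of 11 had an end peak in B73 (exact test, adjusted p = 0.692) and 5 in every founder (adjusted p = 0.265). These included dof1 at 8.63 ± 1.25, nkd2 at 8.52 ± 1.56 and glk1, a regulator of chloroplast development, at 8.35 ± 1.204, while dof36 had no end peak in any founder.

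Defence and pigment genes were split within their pathways, and neither list passed. Of 23 benzoxazinoid and terpene defence genes, 16 had an end peak in B73 (exact test, adjusted p = 0.564) and 9 in every founder (adjusted p = 0.263). The glucosyltransferase genes bx9 and bx8 had 13.8 ± 1.79 and 9.45 ± 1.31, and aos1, an allene oxide synthase of jasmonate synthesis, had 7.36 ± 1.14 (n = 26 each), while bx13 and tps6 had no end peak in any founder. Of 13 anthocyanin and phlobaphene genes, 8 had an end peak in B73 (exact test, adjusted p = 1) and 4 in every founder (adjusted p = 0.692). The chalcone synthase genes whp1 and c2 had 10.3 ± 1.82 and 8.15 ± 1.26, and myb31, whose window also reached another gene, had 9.03 ± 2.18. The pigment regulators c1 and p1 had no end peak in any founder.

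None of the lists of genes of the endosperm, pollen, meristem and plant architecture passed. Of 27 endosperm storage and starch genes, 11 (40.7%) had an end peak in B73 (exact test, adjusted p = 0.134) and 2 (7.41%) in every founder (adjusted p = 0.131). These were esr2 at 14.8 ± 1.85 and o10 at 6.86 ± 1.34 (n = 26 each), and sh1, the sucrose synthase of the shrunken kernel, had 7.25 ± 1.11 in 25 founders, all but Mo18W. A zein gene, az19d2, and betl1, a gene of the basal endosperm transfer layer, were among 9 genes with no end peak in any founder. Of 14 pollen and tassel genes, 9 had an end peak in B73 (exact test, adjusted p = 1) and 1 in every founder (adjusted p = 0.329), ms32 at 13.0 ± 2.02. A peak was present in 25 founders at rop2 and in 24 at ms45, and in none at the pollen expansin genes expb1 and expb10. The windows of ms32 and ms45 also reached another gene.

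Of 18 meristem and KNOX genes, 10 had an end peak in B73 (exact test, adjusted p = 0.940) and 1 in every founder (adjusted p = 0.213), knox6 at 10.2 ± 1.60 (n = 26). A peak was present in 25 founders at wox2a, all but HP301, and in none at the homeobox genes knox3 and lg3. Of 25 plant architecture and domestication genes, 16 had an end peak in B73 (exact test, adjusted p = 0.940) and 5 in every founder (adjusted p = 0.940). The strongest of these were td1, a receptor kinase of meristem size, at 9.58 ± 2.01, d3, a gibberellin synthesis gene, at 8.88 ± 1.29, and br2, an auxin transporter that sets stalk height, at 5.98 ± 1.12 (n = 26 each). The branching genes ba1 and bad1 had no end peak in any founder, and the window of td1 also reached another gene.

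All of the 10 peaks of B73 with the highest fold enrichment lay outside annotated genes, and at least 24 founders had a peak at each. Fold enrichment is taken over the local background, so this ranking favours peaks where that background is low. The background of the 10 ran from 4.198 to 16.7 reads per position, against a median of 16.1 over all B73 peaks. The strongest lay on chromosome 9 (129711325 to 129711720), with a fold enrichment of 28.9, 0.96 kb from the coding gene LOC109942334, and 25 founders had a peak there. The next lay on chromosome 1 (154575677 to 154576273), with 28.0, 41.7 kb from LOC103639666, and on chromosome 10 (1942924 to 1943475), with 27.4, 9.07 kb from LOC103640676. All 26 founders had a peak at both. The others had fold enrichments from 25.4 on chromosome 7 (120423817 to 120424366) to 23.6 on chromosome 2 (213285471 to 213286444). The farthest from a gene lay on chromosome 1 (215902881 to 215903434), 91.1 kb from LOC100277208, and the nearest gene was a lncRNA gene for 1 of the 10, on chromosome 4 (68649983 to 68650413).

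In their own assemblies most founders had slightly more peaks than in B73 coordinates, a comparison added after the file was seen to hold both sets. The number of peaks was 3.33% higher on average (log2 0.05 ± 0.075, SD, n = 25), higher in 16 founders and lower in 9, from -3.85% in HP301 to 16.3% in CML322. Covered length was 5.75% larger on average and larger in 22 of 25 founders. The background level was 19.3% higher on average and higher in 25 of 25 founders, median width was 2.42% larger, and median fold enrichment changed by -3.11% and was lower in 24. The two-sided sign-flip permutation p was 0.00459 for peak number (adjusted p = 0.00459 over the 6 measures compared), and 1e-05, the smallest it can give, for the other measures (adjusted p = 1.2e-05).

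Fresh and frozen nuclei were not compared. The lists of 24 founders hold both states together, and the lists of Mo18W (fresh) and Oh43 (frozen) differ in founder as well as in state.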

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

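The 4 counts below were singled out because they belong to sequences that entered the totals of the lists but no comparison by position, and they lie above 3 peaks, the limit that a count of 0 allows. Most lists pass that limit, so it shows only that scaffolds carry peaks. The counts were chosen after the file was seen. In the own assemblies of 25 founders, 1518 peaks lay on unplaced scaffolds, with a median of 29 per founder. In B73 coordinates, the 26 founders together had 445. The own assembly of CML52 had the most, with 324 peaks on 104 scaffolds, or 0.998% of its list. CML228 followed with 257 peaks on 79 scaffolds, or 0.895%.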

How the results depend on the processing

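The alternatives that used the own assemblies, leaving out B73 or Mo18W and Oh43 for some results, the midpoint, the background level, first names and windows free of other genes were chosen after the data were seen. Of 58 recomputed values of the main results, 47 kept direction and call or stayed within the spread or 1.5 times. A further 10 moved and 1 reversed. Some of the 47 could not have changed, among them values of peak number and its relations with width and fold enrichment. They came from counting every deposited row and from leaving out peaks under 200 bp. Neither altered a list, since lists held 0 repeated intervals and the narrowest peak had 200 bp. Such values say nothing on stability. Of 142 values of single lists and other measures, 123 were kept, 1 moved and 10 reversed. A further 7 passed a threshold that they had missed, and 1 did the converse. The arms contrast, the relations of peak number with width and fold enrichment, and the excess of distal private peaks kept direction and side of the threshold under every alternative run for them. Among the 50% of peaks with the highest -log10 q (from 17.4), the median founder had 18448 peaks and merged regions numbered 51809. Regions of every founder numbered 2627 and regions of 1 founder 10216. The ratio of the most to the fewest peaks was 6.34, against 1.76 without that threshold. The threshold was the same for all lists, while their median -log10 q ran from 9.63 in CML228 to 42.2 in Oh43. It thus removed more than 50% of the peaks of CML228 and less than 50% of those of Oh43. Private regions numbered 32627 with a reciprocal overlap of 50%. The log2 distal share over random (-1.69) was -1.42 with a 1 kb window, -1.55 with the stricter threshold, -1.53 with coding genes and -1.64 with midpoints. With all annotated genes as background, 9 list tests passed, since that background has fewer peaks. The Mantel r of similarity was 0.756 with the overlap coefficient, whose denominator is the shorter list, -0.752 with lists of equal length and -0.703 with these against background level. Differences from other genes that changed sign, in percentage points, were for the stricter threshold -6.06 (C4 genes, every founder), -2.56 and -6.06 (anthocyanin, B73 and every founder), 3.03 (flowering, every founder) and 1.08 (pollen, every founder). They were -1.53 (anthocyanin, B73) and 3.79 (architecture, every founder) with 2 kb windows, 6.36 (meristem, B73) and 0.876 (architecture, every founder) with all genes, and -7.73 (pollen, B73) with windows free of other genes. Of these only the C4 difference had passed its test, and the cause of the changes of sign was not tested. Light harvesting in B73 kept 42.3 points with windows free of other genes (exact test, adjusted p = 0.122, 7 genes). The summit, the replicate block and the leave-one-out of libraries were not run, because the file holds no summit or library. No paired analysis was possible because the 24 founders with fresh and frozen nuclei have both in 1 list, and Mo18W and Oh43 have 1 state each. Whether a peak missing in a founder of low depth was absent or not detectable was not tested.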

Other observations

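The tests and genes in this part were all chosen after the data were seen. Distal regions within 100 kb were counted for the 80 genes of 5 lists of flowering, architecture, meristem, leaf and pigment genes. Of the 17 with no end peak in any founder, 5 (29.4%) had a distal region with a peak in every founder, against 25 of 63 (39.7%) of those with an end peak (Fisher exact p = 0.575). tb1, the branching repressor selected during domestication (chromosome 1, 272330844 to 272332595), had no end peak in any founder, but a distal region 68.2 kb away at lower coordinates (272262011 to 272262608) had a peak in all 26. kn1, the founding KNOX gene of the shoot meristem, had an end peak in 18 founders and distal regions 64.7 and 61.3 kb away in all 26. zcn8, a florigen gene, had an end peak in 14 founders, and a region 26.5 kb away had a peak in 26. lg1, a ligule gene, had an end peak in 3 founders and 3 distal regions within 100 kb in every founder. lg2 and wox9, with no end peak in any founder, had 0 distal regions within 100 kb.

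Distal regions of every founder (2193) lay a median of 9.15 kb from the nearest gene, and 33.6% lay over 20 kb away. Those of 1 founder (6171) lay a median of 15.8 kb away, and 44.0% over 20 kb. The farthest region of every founder lay on chromosome 1 (138964720 to 138966107), 293.8 kb from a gene. Of 49 list genes with an end peak in 20 to 25 founders, Mo18W lacked a peak at 20, CML228 at 12 and CML103 at 10.

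Il14H and P39, both sweet corn lines, alone held 38 regions where their totals gave 8.61, a ratio of 4.42 (simulation p = 1e-04, the smallest it can give, adjusted p = 0.00406, n = 325 pairs). Of these, 25 (65.8%) were distal, against 32.7% of other regions of 2 founders (Fisher exact adjusted p = 0.00014 over 15 pairs). Similar depth was tested in 2 ways that came out differently, the second chosen once the outcome of the first was known: of 139 other pairs at least as close in background level, the highest ratio was 3.97 (CML228 and CML52), within counting error of 4.42, while the median was 1.24 (SD 0.464). Shared segments could place regions near each other, and 15.8% of the 38 lay within 1 Mb of another (p = 0.0330, adjusted p = 0.0824, n = 38), but these were adjacent regions of 3 loci: with regions under 10 kb apart joined, a test added after that outcome, 0 of 35 loci did, against 4.15% ± 4.49 at random, which leaves shared ancestry open. Regions lacked by both alone were 2.25 times the expected number with an adjusted p of 0.0798 (2.49 times in CML228 and CML52, with 126 against 50.7, and 3.40 times in CML228 and CML69, both with adjusted p = 0.00812, n = 325 pairs), so that mixed nuclei or reads, similar depth and shared ancestry cannot be told apart.

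In all, 15 of the 325 pairs alone held more regions than their totals gave at an adjusted p under 0.05, with ratios down to 1.51 in B73 and KI3. These totals take no account of peak strength or depth, and the 139 pairs above had a median ratio of 1.24. The tests of distal share, of regions or loci within 1 Mb and of regions lacked by both were run on each of the 15. The tests of similar depth were run on Il14H and P39 only. The next highest ratios after Il14H and P39 were 3.97 in CML228 and CML52 (34 against 8.56), 2.68 in Ky21 and Oh43 (469 against 174.8) and 2.60 in CML52 and CML69 (39 against 15.0). Of the 15, only Il14H and P39 passed the test with distal regions more frequent than among other regions of 2 founders. Distal regions were less frequent in Ky21 and Oh43 (23.03% against 33.6%, Fisher exact adjusted p = 8.27e-06), in B73 and Oh43 (21.1% against 33.7%, adjusted p = 2.92e-08) and in B73 and KI3 (8.87% against 33.3%, adjusted p = 6.07e-09). These pairs join founders with the highest background levels, from 1.557 in KI3 to 4.742 in Oh43, so depth and pair cannot be told apart. The other 11 pairs did not pass. In most of these 11 the distal share was also higher, up to 56.5% against 32.8% in NC350 and NC358 (Fisher exact adjusted p = 0.0600). Whether pairs differed from each other was not tested. Loci lay within 1 Mb of another more often than at random in Ky21 and Oh43 (53.1% against 39.6%, adjusted p = 0.0150, n = 456), while the other 14 pairs did not pass, with the next lowest adjusted p of 0.0749 in B73 and Oh43 (n = 469) and in B73 and KI3 (n = 122).

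In 9 of 25 founders the own assembly gave fewer peaks than B73 coordinates. Fewer reads placed there could lower the background, and 0 of the 9 had a lower one. The background also depends on the genome size given to the peak caller, which is not stated for either set of lists. Fewer reads placed in the own assembly thus cannot be excluded. Founders with a larger share of peaks at the lowest background in B73 coordinates lost more peaks, with r = -0.734 and rho = -0.853 over 25 founders (permutation p = 2e-05 for r, adjusted p = 8e-05 over 4 relations tried). Without CML277 and CML69, r was -0.784. Reads placed away from their origin in B73 coordinates may be part of it, but whether peaks at the lowest background mark such reads was not tested. In the own assembly the share was higher in some founders, such as CML228 (1.47% against 0.456%). It was lower in others, such as CML69 (0.558% against 1.13%). Peaks at the lowest background were at most 1.13% of a list in B73 coordinates, less than the loss in CML69 (-3.57%), so they could not make up all of that loss. No biological explanation was tested.

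Differences in peak number between founders may be differences in depth: among the 24 founders with 4 samples, log2 background level and log2 peak number had r = 0.918 and rho = 0.863 (permutation p = 1e-05, the smallest it can give). Over all 26 founders the line through depth held 85.2% of the variance, and founders lay between -9.26% (Oh43) and 13.0% (CML69) of it. Depth here is read from the same lists as the peaks. Biological differences between founders in the amount of open chromatin stay open and were not tested.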
